A study of Mus musculus with 20 samples.

How the data were processed

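Cells of the olfactory mucosa were profiled in 20 samples from 10 pools of 3 mice, each pool sorted into a GFP+ and a GFP- fraction. Per the labels' protocols, biotinylated cRNA was made from 50 to 100 ng of RNA and hybridised to Affymetrix Clariom S mouse arrays, and per the submitters' processing notes the arrays were processed with Affymetrix Expression Console. Its version and the method of background correction, normalization and summarization are not given in the sources used here. The deposited values are log2 signals per probe set, as their range shows, and were used as deposited with no further normalization. The table held 28846 rows. The 6640 control rows were left out of the tests, and 22206 probe sets for genes were kept with no filter on dim ones. Of these, 19572 had 1 gene symbol in the probe annotation, none had several and 2634 had none, and all 19572 were matched by Entrez gene ID to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used only for names, for older receptor family names and for which receptors neighbour each other. For gene lists 1 probe set per gene was used, that with the highest mean. The file holds no detection calls, so signal near background says nothing of whether a gene was expressed.

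That GFP+ and GFP- samples of 1 condition and number came from the same mice was taken from the labels, where 30 mice make up 10 pools of 3. No 2 arrays shared more than 0.00901% of their values. The 4 arrays of replicate 5, 1 in each group, had median gene signals from 7.03 to 7.46 where the other 16 arrays had 6.06 to 6.39, and maxima up to 18.65 where the others reached 19.9. As each group held 1 of these arrays, this batch was balanced, and it was tried as a term and by leaving out both pools numbered 5. Within the batch alone there was 1 array per group and so no test. Apart from the arrays of replicate 5, whose mean correlation with their group was 0.941 to 0.965, 3 arrays correlated least with theirs. These were vehicle GFP- 1 (0.895), vehicle GFP+ 2 (0.946) and odor GFP- 2 (0.951), below called the arrays in doubt.

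Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment at 0.05. The differences GFP+ minus GFP- within each pool entered 1 fit for the sort in vehicle pools, the sort in odor pools and the difference between both. Odor was compared with vehicle within each fraction on its 10 samples without a block. Receptors were adjusted over the list alone and over all probe sets. Of 26 gene lists fixed before the data were examined, 24 had at least 2 measured members and were tested with camera at a preset correlation of 0.01 and an estimated one, and with fry, adjusted over lists. The list of class I receptors, written with current symbols, matched none of the older symbols here, and the erythroid list had 1 measured member.

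Odor and vehicle samples share replicate numbers. In GFP+ cells the deviations of same-numbered samples from their group means correlated at 0.25, 0.52, 0.35, 0.16 and 0.86 for numbers 1 to 5, all above the 0.1 set as the limit for pairing, so the blocked result is given beside the main one. Within replicates 1 to 4 these were -0.05, 0.36, 0.37 and 0.25, so part of the pairing came from the arrays of replicate 5. The calls of the blocked fit had been seen before this check was made, though the limit of 0.1 was set beforehand. In GFP- cells number 2 was at -0.38, and the numbers were not taken to pair.

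Named genes followed a rule fixed before the data were examined: S100a5 and Omp always; for the odor effect on enrichment the receptors past the threshold or, with fewer than 10, the 10 with the smallest p, and 5 other genes; for the sort in vehicle pools the 10 highest, the 10 lowest and 5 receptors in each direction; within each fraction the genes past the threshold or the 5 with the smallest p; and up to 4 members of each list by size of change. Taar genes and members of lists follow the last part.

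The code was tested on simulated data with the real means and spreads and 200 changed probe sets. Noise was drawn independently for each probe set, so correlation between genes was not simulated. For the sort in vehicle pools 91 of 100 changes of 4-fold and 26 of 100 of 2-fold were recovered among 22206 probe sets, with 4.88% false calls. For the odor effect on enrichment among 1094 receptors 13.5% of the calls were false, more than the 5% set. The median SE there was 0.493 for receptors and 0.38 for all probe sets with which their variances were moderated. In 100 simulations with no change, at least 1 receptor was called in 12% for that comparison, in 12% for GFP+ cells without the block and in 66% with it. With variances moderated over receptors alone these were 5%, 4% and 18%. When the simulated spreads were not moderated the blocked fit called any in 10%.

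Alternatives were quantile normalization, centring on the median, leaving out the dimmest 25% of probe sets, an intensity trend with robust variances, array weights, a threshold of 0.1, other treatments of the pairing, Omp as a covariate and leaving out each pool. A pseudocount was not needed for log2 values.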

Results

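Gene expression was measured in cells of the mouse olfactory mucosa, sorted by green fluorescent protein (GFP) from animals that carry a tauGFP reporter at the S100a5 locus. S100a5 is a calcium-binding protein whose transcription in olfactory sensory neurons follows their activity, so GFP+ cells are taken as neurons that were recently active. Mice of 7 to 12 weeks were kept in chambers supplied with clean air at 3.1 L/min for 40 h. From 26 h on they received a pulse of 10 s every 20 min of either filtered air (vehicle) or an odorant, which the sample labels name as an artificial cigarette smoke odor. The design text of the series names another odorant, bourgeonal, and the labels of the samples were followed here. The mucosa of 3 mice was pooled, dissociated and sorted into a GFP+ and a GFP- fraction. There were 5 odor pools and 5 vehicle pools, so 20 samples in 4 groups of 5, and 30 mice in all. Each sample was hybridised to 1 Clariom S array, on which 22206 probe sets for genes were analysed. Of these, 1094 belonged to chemosensory receptors of the main epithelium, 1080 of them odorant receptors and 14 trace amine-associated receptors. The number of arrays limits the precision, and values are log2 signals.

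The first question was whether the sort separated neurons by the reporter. In vehicle pools the S100a5 signal was 16.6 ± 0.32 in GFP+ cells and 15.3 ± 0.68 in GFP- cells (SD, n = 5 each), a log2 change of 1.30 (SE 0.36) that was positive in 5 of 5 pools, with an adjusted p of 0.0368 by limma. In odor pools it was 16.91 ± 0.29 against 14.76 ± 0.66 (SD, n = 5 each), a log2 change of 2.15 (SE 0.36, adjusted p = 0.00131 by limma, 5 of 5 pools). The difference between the 2 conditions was 0.85, with a 95% confidence interval from -0.25 to 1.95 and an adjusted p of 1.0 by limma. Omp, the olfactory marker protein of mature sensory neurons, was at 19.17 ± 0.49 in GFP+ and 18.95 ± 0.70 in GFP- cells of vehicle pools (SD, n = 5 each), and its log2 change of 0.22 (SE 0.23, adjusted p = 0.717 by limma) was smaller than the spread between pools and became -0.02 without vehicle replicate 1, whose difference was 1.19. Omp lay 0.09 to 0.61 below the brightest probe set of each array, where signals can saturate, so a lack of change is not shown. The S100a5 call in vehicle pools was close to the threshold and ended under several settings: quantile normalization (log2 change 1.26), an intensity trend, a term for the 4 arrays of replicate 5, which stood apart from the rest (1.14), and without both pools numbered 5 (1.31). It also ended without vehicle replicate 2 (0.99), 3 (1.14) or 5 (1.31) and without odor replicate 1 or 3, which enter through the shared spread.

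**Figure D1:**
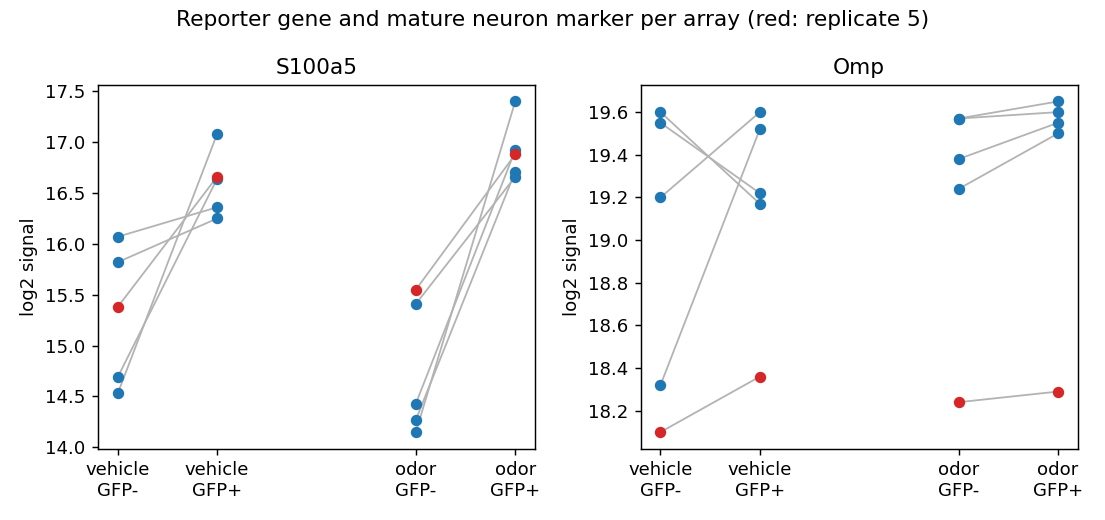
Log2 signal of S100a5 and Omp on each array, with lines joining the GFP- and GFP+ fractions of the same pool and replicate 5 in red. The 5 odor GFP+ samples had a mean S100a5 signal of 16.91 against 14.76 in GFP- cells, while Omp was lowest in each of the 4 groups on the array of replicate 5.

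The sort between GFP+ and GFP- cells of vehicle pools divided the odorant receptors in both directions. Receptors at the top of GFP+ enrichment were Olfr110 (log2 change 5.54, SE 0.33), Olfr481 (5.36), Olfr494 (5.26), Olfr309 (5.17) and Olfr536 (5.13), each higher in 5 of 5 pools. Olfr533, Olfr222, Olfr981, Olfr424 and Olfr695 followed with log2 changes from 4.73 to 4.54, so that all 10 of the highest named genes were odorant receptors. Other receptors were far higher in GFP- cells: Olfr1507 had a log2 change of -7.81 (SE 0.28), Olfr1297 of -7.71, Olfr794 of -7.49, Olfr1406 of -7.23 and Olfr677 of -7.04. The Olfr1507 signal was 13.61 ± 0.87 in GFP- and 5.80 ± 0.93 in GFP+ cells (SD, n = 5 each). The lower mean of Olfr481 (4.81), Olfr494 (5.02), Olfr981 (5.15), Olfr1507, Olfr794 (4.31), Olfr1406 (4.11) and Olfr677 (4.71) lay within or below the range of the background control medians, 5.14 to 6.34 per array, so their changes are lower bounds and the order of the receptors is not measured. Of the 1080 odorant receptors 364 rose and 170 fell in GFP+ cells, and adjusted over the list alone 460 rose and 205 fell. Of the 14 trace amine-associated receptors, which detect volatile amines, 5 rose and 3 fell, with Taar4 at 3.45 and Taar9 at 2.51 against Taar2 at -2.60. Together these receptors made up 73.7% of the 501 probe sets that rose in GFP+ cells, and their changes had an SD of 1.99 against 0.76 for other probe sets. By camera with a preset correlation the odorant receptor list lay higher in GFP+ cells (adjusted p = 8.8e-07), a call that was lost with an estimated correlation (adjusted p = 0.366).

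Genes of white blood cells were the largest difference in the other direction. Lcn2, which binds bacterial siderophores, was at 18.14 ± 0.75 in GFP- and 6.90 ± 1.12 in GFP+ cells (SD, n = 5 each), a log2 change of -11.24 (SE 0.44). Ngp, a neutrophil granule protein, had a log2 change of -11.06, the calcium-binding proteins S100a8 and S100a9 of -10.74 and -9.89, Retnlg of -10.72 and Chil3 of -9.73. Ly6c2, Ly6e, Mmp8 and Ly6c1 lay between -8.49 and -8.21. Each was lower in GFP+ cells in 5 of 5 pools, with adjusted p-values by limma of 4.2e-08 or less. In GFP+ cells the means of S100a9, Retnlg, Chil3, Ly6c2, Mmp8 and Ly6c1, from 4.78 to 6.11, lay within or below the range of the background control medians, so their changes are lower bounds, while Ngp was at 7.42 and Ly6e at 8.71. In GFP- cells Ngp on 2 vehicle arrays and S100a8 on 1 lay as near the brightest probe set as Omp, so their changes are lower bounds too. Of 16 measured immune cell genes 14 fell, among them Lyz2 (-7.71) and Itgam (-6.52), and the list was lower with a preset and with an estimated correlation (adjusted p = 9.7e-28 and 0.00748). The inflammation and mucosal defence list fell in 5 of 12 members, with Il1b at -5.98 and Tnf at -2.69 beside Lcn2 (adjusted p = 0.0196 with an estimated correlation).

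Genes listed for earlier stages of the neuronal lineage were also lower in GFP+ cells. Of 11 measured genes of globose basal cells and cycling progenitors 6 fell, including the proliferation marker Mki67 (log2 change -5.33), the receptor tyrosine kinase Kit (-3.91) and Top2a (-2.07), and the list was lower with an estimated correlation (adjusted p = 0.0196). Of 14 immature neuron genes 7 fell, including Gng8 (-4.37), Dpysl3 (-3.32) and Stmn1 (-2.55), with an adjusted p of 3.7e-06 with the preset correlation and 0.0819 with an estimated correlation. None of 17 mature neuron genes passed the test, with Pde1c at 0.98 and Ano2 at 0.83, while 2 passed with quantile normalization and 2 with each array centred on its median, and the list's adjusted p was 0.00442 with the preset and 0.476 with an estimated correlation. Of these genes Stoml3 on 20 arrays, Gnal on 16 and Ric8b on 1 lay as near the brightest probe set as Omp. Activity-associated genes of sensory neurons were higher in GFP+ cells: 5 of 11 rose (3 with quantile normalization and 6 with centring), S100a5 itself among them, with Pcp4l1 at 2.12, Lrrc3b at 1.94 and Sema7a at 1.83, and with an adjusted p of 0.00117 with the preset and 0.26 with an estimated correlation. Of 15 immediate early genes, which respond within minutes to many stimuli, 8 fell in GFP+ cells, including Egr1 (-6.78), Fos (-5.24), Egr2 (-4.78) and Btg2 (-4.14), and the list was lower with an estimated correlation (adjusted p = 0.0196). Genes of white blood cells fell in the same comparison with a median of -4.31. The cells that carry the immediate early, progenitor and immature neuron transcripts were therefore not identified.

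Markers of other cells of the mucosa moved to different extents. Of 13 microvillar and tuft-like cell genes 9 fell, including the channel Trpm5 (-4.45), Hepacam2 (-4.53) and Foxi1 (-2.90), with an adjusted p of 0.0196 with an estimated correlation. Of 12 genes of guanylyl cyclase D and Ms4a sensory neurons 5 fell, with Ms4a4c at -4.00, Ms4a6b at -2.98 and Pde2a at -2.46 (adjusted p = 0.0196 with an estimated correlation), and Ms4a genes are also known from white blood cells. Among Bowman gland and secretory genes Ltf (-7.16), Sox9 (-4.09) and Bpifa1 (-1.03) fell (2 with quantile normalization and 2 with centring), the median of 12 members was 0.09 and their mean -0.97, and the list's adjusted p of 0.0403 became 0.345 with an estimated correlation. Ltf is also a granule protein of neutrophils. Of 12 sustentacular cell genes 2 fell (3 with quantile normalization and 1 with centring), Sult1c1 (-2.45) and Cyp1a2 (-1.50), with an adjusted p of 0.00434 that became 0.366 with an estimated correlation. Pecam1 (-1.17) was the 1 of 9 endothelial and stromal genes to fall and Erbb3 (-1.07) the 1 of 7 ensheathing glia genes, and both lists had 0 such calls with quantile normalization and with centring. The endothelial list had a median of 0.13 and a mean of -0.13, and the median of the glia list, -0.06, became 0.19 with each array centred on its median. None of 8 horizontal basal cell genes passed, and none of 8 ciliated cell genes, where each of those scalings called 1 higher. Of 63 cytosolic ribosomal protein genes 23 fell, with Rplp0 at -1.88 and Rps16 at -1.74 (adjusted p = 1.3e-17 with the preset and 0.0819 with an estimated correlation), and 14 fell with each array centred on its median. In oxidative phosphorylation 1 of 77 genes rose, Cyc1 (0.92), against 2 with quantile normalization and 5 with centring, and the list's adjusted p of 0.0285 became 0.6 with an estimated correlation. Heat shock genes Hspa1b (-2.93), Hspa1a (-2.31) and Dnajb1 (-0.94) fell among 11 measured (2 with each of those scalings), with an adjusted p of 0.0403 that became 0.184 with an estimated correlation. The interferon list had 1 of 9 genes lower, Bst2 (-1.29), and 0 with quantile normalization, while with centring 1 was higher and 1 lower. Of 319 vomeronasal receptors 1 was higher, Vmn2r3 (0.92), against 6 with quantile normalization and 13 with centring. None of 13 xenobiotic and oxidant response genes and none of 3 sex-linked genes passed.

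**Figure D2:**
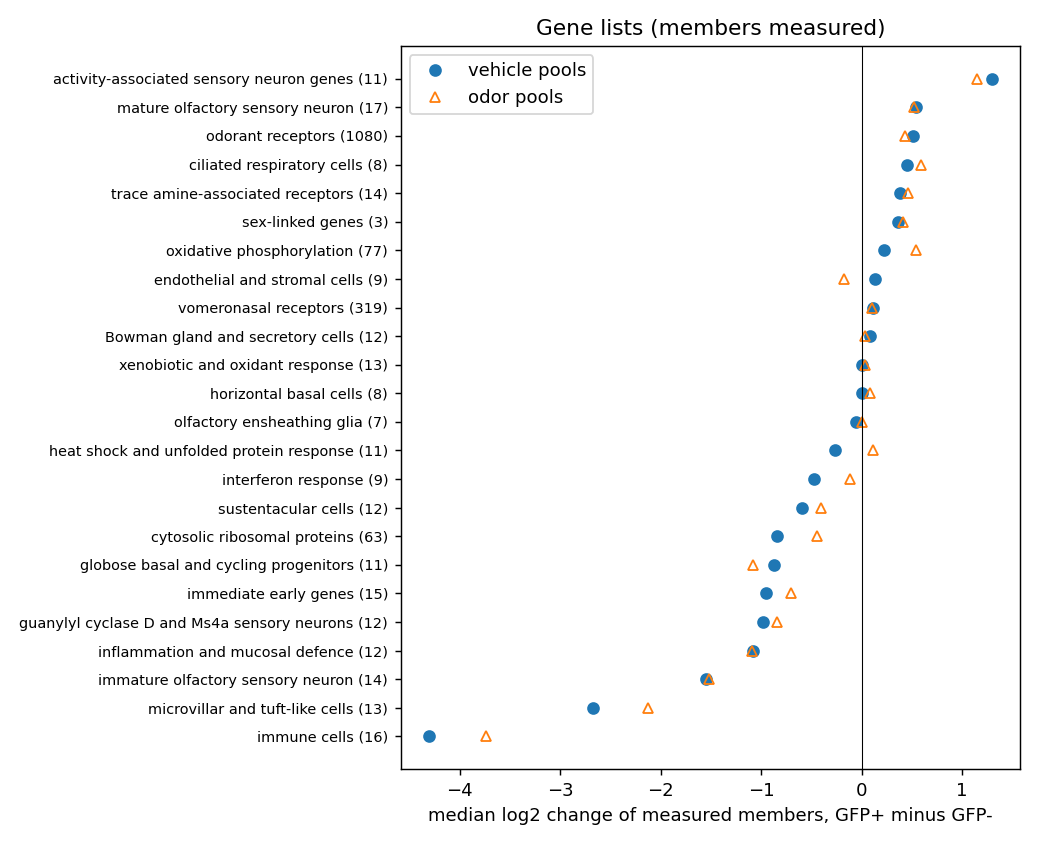
Median log2 change between GFP+ and GFP- cells over the measured members of each gene list, with the number of members in brackets, in vehicle pools (filled circles) and odor pools (open triangles). The immune cell list had the lowest median in both, -4.31 in vehicle and -3.74 in odor pools.

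In all, 501 probe sets rose and 1523 fell in GFP+ cells of vehicle pools among 22206 tested with limma on the differences within pools. With each array centred on its median the split was 1169 higher and 1211 lower, as that scaling moved the median of all probe sets from 0.09 to 0.33, and without vehicle replicate 2 it was 786 and 1530. In odor pools it moved from 0.08 to 0.29.

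The same comparison in odor pools gave 460 probe sets higher and 1292 lower. Olfr110 (log2 change 5.42), Olfr536 (5.97) and Olfr309 (5.60) were again higher in GFP+ cells in 5 of 5 pools, and Olfr1507 (-8.89) and Olfr1297 (-7.99) lower. Olfr1507 in odor GFP+ cells, at 4.71 to 6.37, lay at the level of the background control medians, 5.14 to 6.34, so its change is a lower bound. Lcn2 was at -11.00 and Ngp at -10.50. Of the odorant receptors 329 rose and 185 fell, and adjusted over the list alone 419 rose and 231 fell, while of the trace amine-associated receptors 6 rose and 1 fell. The list of odorant receptors had an adjusted p of 0.000362 with the preset and 0.509 with an estimated correlation. Across the 1094 receptors the changes in vehicle and in odor pools, which came from different mice, had a Pearson r of 0.97 and a Spearman rho of 0.952, where genes are not independent replicates. Of the receptors, 306 rose in both conditions where independent lists would share 113, and 159 fell in both where they would share 29.4. No receptor that passed in both did so in opposite directions. Immune cell genes fell in 12 of 16 cases and microvillar genes in 9 of 13 (adjusted p = 0.00791 and 0.0189 with an estimated correlation). In oxidative phosphorylation 3 of 77 genes rose, against 1 with quantile normalization and 11 with centring, and the list's adjusted p was 8.2e-09 with the preset and 0.219 with an estimated correlation. Of 63 ribosomal protein genes 5 fell (2 with centring), with a median of -0.45 against -0.84 in vehicle pools and an adjusted p of 9.8e-09 with the preset and 0.237 with an estimated correlation. The median difference between odor and vehicle pools, 0.39, had an adjusted p of 3.2e-09 with the preset and 0.642 with an estimated correlation. Without both pools numbered 5, whose 4 arrays stood apart from the rest, the counts were 1236 in odor and 1483 in vehicle pools.

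**Figure D3:**
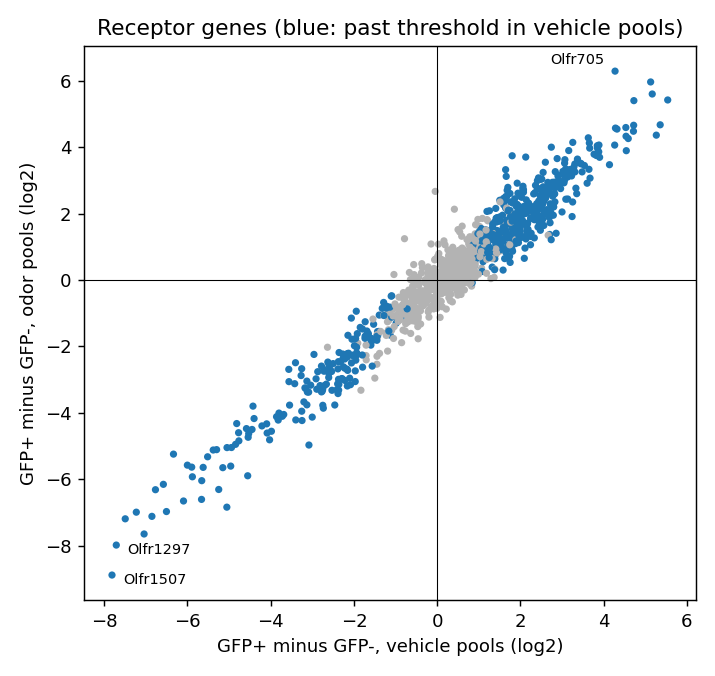
Log2 change between GFP+ and GFP- cells for each of 1094 receptor probe sets, in vehicle pools (horizontal axis) and odor pools (vertical axis), with those past the threshold in vehicle pools in blue. The points follow the diagonal with a Pearson r of 0.97 across genes.

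The main question of the design was which receptors gained GFP+ enrichment with the odor. No receptor did so past the threshold: the pool differences of 5 odor and 5 vehicle pools gave 0 of 1094 receptors adjusted over the list alone and 0 of 22206 probe sets by limma. At an unadjusted p under 0.05 there were 45 receptors, or 4.11%, and 269 probe sets, or 1.21%. The receptors with the smallest p-values had adjusted p-values of 0.999 over the list alone by limma. They were Olfr1153 with a difference of 1.46 (95% confidence interval 0.68 to 2.25), Olfr705 with 2.02 (0.80 to 3.24), Olfr1257 with 1.94 (0.75 to 3.13), Olfr1202 with 2.72 (0.84 to 4.59), Olfr1281 with 1.58 and Olfr478 with 0.87, and on the other side Olfr203 with -1.53, Olfr859 with -1.20, Olfr843 with -1.07 and Olfr1107 with -1.02. Olfr1202 and Olfr705 passed over the list alone with array weights (differences of 3.22 and 2.50) and without vehicle replicate 1 (3.60 and 2.52). Among other genes the smallest p-values belonged to Pglyrp1, a peptidoglycan recognition protein (1.23), 5430402E10Rik (1.07), Nckap5l (0.94), Wfdc9 (-1.05) and the chemokine Ccl27a (1.07). Signals of Wfdc9 (3.17 to 5.51) and 5430402E10Rik (3.87 to 6.19) lay within or below the range of the background control medians, 5.14 to 6.34. Those of Nckap5l (5.04 to 6.83) lay near it, so changes of these genes are not shown. In GFP- cells some signals of 5 of the receptors also lay within or below that range. These were Olfr1153 (5.40 to 8.21), Olfr705 (5.87 to 10.17), Olfr1202 (4.345 to 9.98), Olfr478 (5.25 to 7.10) and Olfr203 (4.20 to 7.92). The sizes of their differences are therefore not well measured. In 1 simulated data set with 200 of the 1094 receptors changed, this comparison recovered 83 of 100 changes of 4-fold and 26 of 100 of 2-fold. With 200 changed among all 22206 probe sets it recovered 60 and 7. An odor acting on only a few receptors was not simulated, so these shares do not give the chance of finding its receptors. Lists of ribosomal proteins (median 0.39), oxidative phosphorylation (0.37), immune cells (0.46) and inflammation (0.30) lay higher and odorant receptors (-0.13) lower with the preset correlation, and none with an estimated correlation, where the smallest adjusted p was 0.642.

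Odor and vehicle were then compared directly within GFP+ cells. No probe set and no receptor passed the threshold by limma without a block. At an unadjusted p under 0.05 there were 61 probe sets (0.275%), 15 of them receptors (1.37% of all receptors). With no change such a limit gives 5% on average. The unblocked fit leaves the offset of the replicate 5 arrays in the spread. Its median SE over all probe sets was 0.36, against 0.21 with the block. The lack of calls therefore says little on whether odor changed expression. The smallest p-values belonged to Olfr1257 (log2 change 1.46, SE 0.23, adjusted p = 0.0524 over the list alone), Olfr1186 (1.74), Olfr1181 (1.36), Hspa1l (0.73) and Olfr328 (1.13), each higher with odor in 5 of 5 same-numbered pairs. Hspa1l lay at 3.70 to 4.85 in GFP+ cells, below the lowest background control median of 5.14, so a change of the gene is not shown. Vehicle GFP+ signals of Olfr1186 (5.03 to 6.87) and Olfr1181 (4.99 to 7.00) overlapped the background range, so their changes can be lower bounds. At an unadjusted p under 0.05 the fit with the replicate number as a block had 820 probe sets. Of the receptors 157 (14.35%) were under that limit, 82 higher and 75 lower with odor. In this blocked fit 6 receptors passed over the list alone and none over all probe sets by limma. These 6, chosen after their values were seen, were Olfr1257 (1.46, SE 0.18), Olfr220 (1.68), Olfr314 (1.68), Olfr1281 (1.38), Olfr1183 (1.67) and Olfr1181 (1.36), with adjusted p-values from 0.00448 to 0.0219. In GFP- cells their changes with odor ran from -0.48 to 0.66 with the block. The odor effect on their enrichment ran from 0.91 to 1.94, and none passed there. For Olfr1181 GFP+ minus GFP- in odor pools ran from -2.59 to 0.05, so it was not enriched in GFP+ cells. Enrichment of Olfr1183 in odor pools was not shown either, with a log2 change of 0.17 (SE 0.62), positive in 3 of 5 pools. Olfr220 (1.085) passed in that sort over the list alone (adjusted p = 0.0284 by limma) but not over all probe sets (0.149). Olfr1257 (3.743), Olfr1281 (3.704) and Olfr314 (1.518) passed over all probe sets, though the Olfr314 call ended under several settings. Olfr1257 was at 13.64 ± 0.34 in odor and 12.18 ± 0.14 in vehicle samples (SD, n = 5 each). In 100 simulations with no change the blocked fit called at least 1 receptor in 66% with moderated and in 10% with unmoderated spreads. The rate set was 5%, and 6 or more were called in 2% and 0%. These simulations drew each gene independently, while odorant receptors had an estimated correlation of 0.05 in this fit. They therefore do not give the chance of 6 calls in the real samples. With variances moderated over the receptors alone, an alternative chosen after seeing the data, 3 of the 6 passed (Olfr220, Olfr314 and Olfr1257, adjusted p = 0.0425 by limma for each). Part of the pairing of same-numbered samples came from the arrays of replicate 5, without which the correlation for number 1 was -0.05 and those for numbers 2 to 4 stayed above 0.1. With a term for these arrays in place of the block Olfr220 and Olfr1257 passed. Without both pools numbered 5 and without the block, the same 2 receptors passed. The list of mature neuron genes had a median of 0.18 and vomeronasal receptors one of -0.04, each with an adjusted p of 0.0219 with the preset and 0.979 with an estimated correlation.

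**Figure D4:**
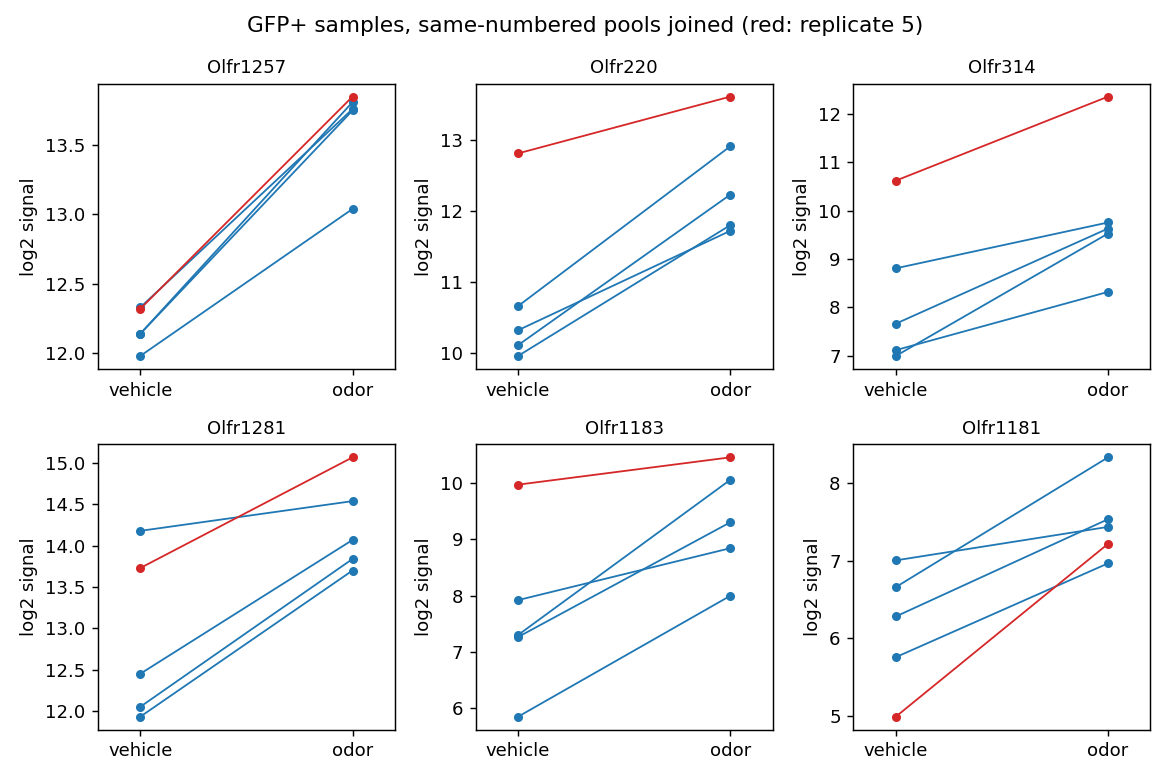
Log2 signal in GFP+ samples of the 6 receptors past the threshold with the replicate block, with lines joining vehicle and odor pools of the same number, replicate 5 in red and an axis of its own in each panel. The mean change per receptor ran from 1.36 to 1.68 and every line rises.

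Within GFP- cells no probe set and no receptor differed between odor and vehicle past the threshold by limma, with or without the block. At an unadjusted p under 0.05 there were 30 probe sets without and 190 with the block, and 3 and 28 receptors. The smallest p-values without the block belonged to Esp16 (log2 change -0.88), Olfr705 (-1.70), the transcription factor Nfe2 (-1.06), Retnlg (-1.01) and B2m, a component of class I histocompatibility molecules (-1.16). The immune cell list had a median of -0.64, ribosomal proteins -0.31 and oxidative phosphorylation -0.25, and mature neuron genes 0.27 and odorant receptors 0.12. These lists passed with the preset correlation (adjusted p = 1.8e-08 for immune cells) and none with an estimated correlation, where the adjusted p for immune cells was 0.344. S100a8 was at -0.88, Fcer1g at -0.77 and Tyrobp at -0.77, none past the test.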

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

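Of 132 groups of 5 values examined, 11 held a sample far from the others by Dixon's test, where chance gives about 6.6, and 8 of the 11 were samples of replicate 5. The tests of the replicate 5 arrays, of the share of neurons and of other non-neuronal cells, the tests of the immune list within replicates 1 to 4 and of its genes above background, and the 3 counts of splits for results of 0 were chosen after the results were seen.

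The arrays of replicate 5 stood apart in the median log2 signal, at 7.07 for odor GFP+ (others 6.08 to 6.19), 7.46 for odor GFP-, 7.03 for vehicle GFP+ and 7.40 for vehicle GFP-. Omp on these arrays was at 18.29 in odor GFP+ (others 19.5 to 19.65) and 18.24 in odor GFP- cells. The Olfr220 signal of vehicle GFP+ 5 was 12.81 against 9.96 to 10.66, and the Ly6c1 difference of vehicle pool 5 was -9.72 against -7.97 to -7.63. The Chil3 difference of odor pool 3 was -8.17 against -9.50 to -9.34, the Olfr1297 difference of vehicle pool 2 was -9.18 against -7.49 to -7.22, and the Olfr1257 signal of odor GFP+ 1 was 13.04 against 13.75 to 13.85.

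Among 6 receptors higher in GFP+ cells of odor pools with the replicate block, the mean over replicates 1 to 4 of the median change was 1.63 (SE 0.18). This decides nothing about the batch of replicate 5, as the 6 were called for rising in all 5 pairs. In the blocked fit without both pools numbered 5, Olfr220, Olfr1183, Olfr1257 and Olfr314 passed, while Olfr1281 (1.39) and Olfr1181 (1.14) did not. For the same reason this is no separate support, and within replicates 1 to 4 number 1 did not pair (-0.05). With neither the block nor the pools numbered 5, of the 6 only Olfr220 and Olfr1257 passed. The median change of the other receptors was -0.0396 (SE 0.071) and that of all 1094 was -0.05, so receptors did not rise as a whole. Setting the others against the 6 decides little on the share of receptor neurons. The 6 were the only receptors called, and a like rise in the others would have brought more calls. Signal shared between similar receptors stays open: 2 of the 6 (Olfr1257 and Olfr1183) had a family member above a log2 change of 1, which met the bound set beforehand against it, but that bound left out the error, and after the result was seen it was judged too weak, as the largest changes in the other families, 0.60 to 0.92 with SE from 0.20 to 0.33, do not exclude 1. The 16 splits within numbers are too few for a share under 0.05: the real split gave 6 receptors and 1 of the 16 splits, the real one, gave as many, with 4 in the highest other. An effect of the odor is the untested biological candidate explanation. The false calls in the simulations are a limit on it, and with correlated genes their rate is not known.

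In GFP- cells the immune list mean was 9.80 ± 0.69 in odor and 10.31 ± 0.39 in vehicle pools (SD, n = 5 each), lower in 4 of 5 pairs, with p = 0.175 in a two-sided exact permutation test. Within replicates 1 to 4, apart from the batch of replicate 5, the difference was -0.67 (SE 0.17), with odor from 9.24 to 9.69 and vehicle from 9.83 to 10.48 (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). The vehicle GFP- array of replicate 1 had the lowest mean of the vehicle samples, 9.83, and leaving it out could only widen the difference, to -0.64 (SE 0.35), which missed the bound of more than 2 SE below 0 set beforehand. Relative to the other non-neuronal lists the immune list was at -0.42 (SE 0.19, exact permutation p = 0.0714), and at -0.55 (SE 0.17, exact permutation p = 0.0571) within replicates 1 to 4, yet only 17 of 69 genes of the other lists lay more than 2 above background, and over these and 11 such immune genes the value was -0.51 (SE 0.35, exact permutation p = 0.183), so a lower share of all non-neuronal cells stays open. Whether the odor lowers white blood cells in this fraction stays open too.

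For the 2 sort comparisons the 16 splits that part every pool are too few for a share under 0.05. The real counts were 2024 in vehicle pools, with 17 in the highest other split, and 1752 in odor pools, with 0 in the highest other, and in each only 1 of the 16 splits, the real one, gave as many. For the comparisons with a count of 0, each of the 100 drawn splits necessarily gave as many, so this decides nothing. Other splits called up to 104 receptors for the odor effect on enrichment, 47 in GFP+ and 361 in GFP- cells. Of the 126 possible splits 56 put both pools numbered 5 on 1 side, which carries their batch into the comparisons within a fraction. Splits that part these pools were not counted apart, so the source of these calls was not tested.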

How the results depend on the processing

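Leaving out the arrays of replicate 5 or the 3 arrays in doubt, the term for replicate 5, moderation over receptors alone and all alternatives of the blocked count were chosen after seeing the data. The odor effect on enrichment of all genes and the comparison within GFP- cells gave 0 calls under each alternative run. The replicate block was run within each fraction and, without list tests, for the odor effect on enrichment, but not for the sort comparisons. Within the fractions it changed the call of receptors in GFP+ cells. With the preset correlation it also changed that of the activity-associated list in GFP- cells, where 6 lists passed in place of 5. It changed no other call there, and for the odor effect on enrichment, where numbers did not pair, it gave 0. For receptor enrichment array weights gave 2 receptors, and leaving out 1 pool gave 0 to 2. In GFP+ cells array weights called 1 probe set. For receptors in GFP+ cells over the list alone, a threshold of 0.1 gave 1, array weights 4, the replicate block 6, a term for replicate 5 gave 2, leaving out both pools numbered 5 gave 2, and leaving out 1 sample 0 to 1. The blocked count of 6 became 0 adjusted over all probe sets, 3 with moderation over receptors alone, and 6, 8, 4, 3 and 4 without replicates 1 to 5, of which 4, 6, 4, 3 and 4 were among the 6; the 8 held 2 lower ones. In the sort, treating the 20 samples as 4 groups with no replicate block called 1198 probe sets in vehicle and 1050 in odor pools, and array weights 3366 in odor pools, of which 41.4% were higher. Other totals stayed within 1.5 times, with 1532 to 2316 in vehicle and 1296 to 2127 in odor pools on leaving out 1 pool. Centring on the median moved the share of higher calls from 24.8% to 49.1% in vehicle and from 26.3% to 43.3% in odor pools, as it shifts all probe sets. With an estimated correlation the lists called fell from 15 to 6 in each sort comparison, from 5 to 0 for the odor effect on enrichment, from 2 to 0 in GFP+ and from 5 to 0 in GFP- cells. Except where stated the cause was not tested. Of 2259 values of named genes under alternatives 2198 kept direction and side, 22 passed anew, 18 were lost and 21 not past the threshold changed sign. S100a5 in vehicle pools and Olfr314 in odor pools account for most of the losses. S100a5 was at 0.99 without vehicle replicate 2. The Olfr314 call between GFP+ and GFP- cells ended without odor replicate 1 (1.44), 2 (1.32), 4 (1.55) or 5 (1.525). It also ended with the term for replicate 5 (1.51) and with no replicate block (1.52). The pool mean of Xist as a covariate was not run, as the gene is unnamed here, nor were pseudocounts. Signal near background limits the size of large folds.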

Other observations

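The tests on neighbouring receptors, receptor classes and the fractions were set out before their results were seen, while the splits that part the pools numbered 5 and those within numbers were chosen afterwards for the test on the fractions.

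The older family names of the receptors gave 121 class I and 940 class II receptors, which differ in sequence and in where they are expressed in the epithelium. In vehicle pools 29 class I receptors rose in GFP+ cells and 10 fell, and 330 class II receptors rose and 155 fell. The hypothesis that the classes differ in enrichment was not borne out for the medians, which were 0.45 and 0.52. Their difference of -0.0671 lay inside the range of shuffled classes from -0.30 to 0.35 (permutation p = 0.68). As receptors moved in both directions, medians do not compare the shares that passed. That share was smaller in class I, also in odor pools (26 rose and 13 fell, against 297 and 168 in class II). The difference in shares was not tested.

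Receptors that neighbour each other on a chromosome had similar changes between GFP+ and GFP- cells in vehicle pools, with a correlation of 0.15 over 1077 neighbouring pairs across genes (permutation p = 1e-04, the smallest that 10000 shuffles can give). Between neighbours of different families it was 0.0746 (n = 416, p = 0.063 by permutation) and of the same family 0.21 (n = 611). Signal shared between similar receptors may therefore account for this, and common regulation of related genes was not told apart from it. The odor effect in GFP+ cells was similar between neighbours too, at 0.19, and at 0.16 between families, yet 3 of 16 splits within numbers gave a correlation as high, up to 0.23, so differences between pools unrelated to odor could give it.

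If odor moved cells of responding receptors from the GFP- to the GFP+ fraction, the odor effects in both fractions would be opposed across receptors. Their correlation across the 1094 receptors was 0.0869, above the 0 set beforehand as the bound against such a shift, but by less than its spread. In the 70 splits that part the pools numbered 5, as the real one does, it had an SD of 0.142 and a median of 0.11, and 30 gave one as low. In the 16 splits within numbers it ran from -0.14 to 0.23, and 11 gave one as low, so a shift stays open.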
